A study of Macaca mulatta with 42 samples.

How the data were processed

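Whole blood of 42 female rhesus macaques was incubated with Gardiquimod for 4 h, white cells were collected and poly(A) RNA libraries were made with 13 PCR cycles and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name Trim Galore 0.2.7, STAR, HTSeq 0.6.1, edgeR and limma. The genome build and gene annotation were not given in the sources used here. The deposited table holds whole-number counts of reads per gene, without normalization, as the values themselves show: 16049 gene rows and 5 rows of HTSeq counters for 42 libraries, with no further columns. The counter rows were kept out of library sizes and tests. Over all libraries they held 60.2% of reads: 35.4% aligned to more than 1 place, 23.2% lay in no annotated feature and 1.62% were ambiguous, while the unaligned and low-quality counters were at 0%. Reads shared between near-identical gene copies thus fall outside the gene counts, and gene families with such copies are under-counted. Whether counting used the strand was not given in the sources used here, so overlapping antisense genes cannot be told apart.

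The rows are numbered. Of the 16049 identifiers, 0 matched the RefSeq macaque gene table and 0 matched the Ensembl name table used here, so no gene is named. The rule fixed for naming genes took the 10 of smallest p in each direction among those with a symbol, for current rank, past rank and their interaction, and 4 per direction for age, flowcell and the difference of slopes. With no symbols it named none. In its place the 2 identifiers of smallest p in each direction are given for past rank and for current rank with social group in the fit. For each rank this was the fit that gave calls. The additive fit was the main fit planned for both, and taking current rank identifiers from the other was decided after the data were seen. The 22 gene lists (486 entries), their set tests and the marker list scores were not computed, since no table used here pairs these numbers with symbols.

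Each library was assigned to its social group, ratings, age, flowcell (run0316, 20 libraries; run0317, 22) and 11 white cell percentages from the deposited labels. Percentages of white cells are per the labels, measured by the authors. Replicate numbers within a social group follow the order of the deposit and only name animals.

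The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, robust dispersion, and genes kept by filterByExpr (12223 of 16049; 639 identifiers had no read in any library). The additive model held standardised current Elo, past Elo and age, flowcell, and the first 3 principal components of the 11 standardised cell percentages (60.3% of their variance), leaving 34 residual degrees of freedom. The first component set NK, NK T and activated monocyte percentages against polymorphonuclear cells, the second set T and B cells against them, and the third was mainly double-positive T cells. Benjamini-Hochberg adjusted p under 0.10 was the threshold. Slopes are log2 units per SD. The interaction test added the product of both ratings; the social group test took 8 group coefficients in place of past Elo. Variance inflation was 1.26 for current Elo, 1.63 for past Elo and 2.61 for age, and 1.52 and 4.81 for the ratings with social group added. Relations across animals used Pearson's r and Spearman's rho with 100000 two-sided permutations, made within social groups where values were centred on group means, and comparisons of highest- with lowest-rated females used all sign flips of 9 pairs.

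The alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, limma 3.58.1 voom, other count filters, 0 or 5 cell components, social group as coefficients or as a random effect, no age or flowcell term, each flowcell alone, ordinal rank, thresholds of 0.05 and 0.20, and leaving out each animal or social group. Chosen after the data were seen were the share of identifier 3043 as a covariate, its removal, leaving out the 5 libraries with over 50% multi-mapped reads, all settings of the fit with social group, the fits on single cell percentages, the sets of 50 identifiers and all relations with age. Figures and correlations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

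The test was checked on simulated counts for 12223 genes, with 50 changed along current rank at each slope. The additive fit recovered 20% of slopes of 0.25, 66% of 0.5, 96% of 1 and 100% of 1.5, with 10 false calls among 151. With social group in the fit it recovered 14%, 72%, 98% and 98%, with 4 false calls among 145. Simulated genes were drawn independently of each other, with no effect of social group, age or cell composition. These false calls therefore do not measure error control in the real libraries. Depth per library was 6371183 to 14412905 gene reads, and 3612781 to 13376449 without identifier 3043, so libraries in which that identifier is abundant measure the other genes with larger counting error. PCR reads without molecular identifiers are not independent molecules.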

Results

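Gene expression was measured in the white blood cells of 42 female rhesus macaques (Macaca mulatta), with 1 library per female. All libraries came from whole blood incubated for 4 h with Gardiquimod, a synthetic ligand of the RNA-sensing receptor TLR7, at 1 µg/ml. The females lived in 9 social groups, 6 of 5 animals and 3 of 4. Each had a current Elo rating, a score of social rank in which a higher value means a higher rank, and a past Elo rating from the earlier phase of the study. Current ratings ran from -126 to 1997 (mean 1065 ± 676, SD, n = 42) and past ratings from 30 to 1908 (mean 1000 ± 534, SD, n = 42). Ages ran from 4.52 to 21.48, with no unit in the labels. The series title asks how present rank, rank history and pathogen signals relate to gene regulation. Blood incubated without the ligand or with other stimuli was not analysed here, so every comparison lies within the TLR7-stimulated state and the response to the ligand itself was not measured.

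Libraries held between 6371183 and 14412905 reads assigned to genes (median 10265904), and between 11884 and 13746 identifiers with at least 1 read. The table lists genes by number, and the files do not pair these numbers with names, so genes are given below as identifiers. The 22 gene lists written before the data were examined, among them interferon-stimulated genes, inflammatory cytokines and blood cell markers, were not tested for the same reason. No 2 libraries agreed within sampling noise: over 861 pairs the smallest chi-square per degree of freedom was 27.

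Expression of many identifiers followed blood cell composition. Expression of 4101 of 12223 tested identifiers followed the percentage of polymorphonuclear cells, 2086 higher and 2015 lower in females with more of them. The percentage of helper T cells was followed by 2653 identifiers, 1174 of them positively. Cytotoxic T cells were followed by 1249 identifiers, of which 881 were lower where these cells were more abundant, and NK T cells by 800. CD8-negative B cells were followed by 39 identifiers, 38 of them positively. NK cells were followed by 10 identifiers and double-positive T cells by 1. Neither classical monocytes, CD14-positive activated monocytes, CD14-negative activated monocytes nor CD8-positive B cells were followed by any identifier at an adjusted p under 0.10 in edgeR (751, 522, 1883 and 941 at an unadjusted p under 0.05) or in limma voom. These 11 fits each held 1 cell percentage with both ratings, age and flowcell, but not social group. They were added after the data were seen. The percentages depend on each other: on the second component helper T (0.468) and cytotoxic T cells (0.398) stood against polymorphonuclear cells (-0.42). Overlap of the identifiers called for different cell types was not examined. The counts therefore cannot be read as specific to 1 cell type. Of the variance of the NK T percentage 63.5% lay between social groups, against 19.5% for groups with no effect. For NK cells this was 42.7%, and for polymorphonuclear, helper T and cytotoxic T cells 14%, 8.19% and 11.8%. The 800 NK T and 10 NK calls therefore cannot be told apart from other differences among social groups. With limma voom the NK T count was 375, the NK count was 0 and the double-positive T count was 14. With ranks in place of the percentages in edgeR, the NK T count was 515 and the NK and double-positive T counts were 0. CD14-negative activated monocytes were then followed by 2 identifiers.

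**Figure D1:**
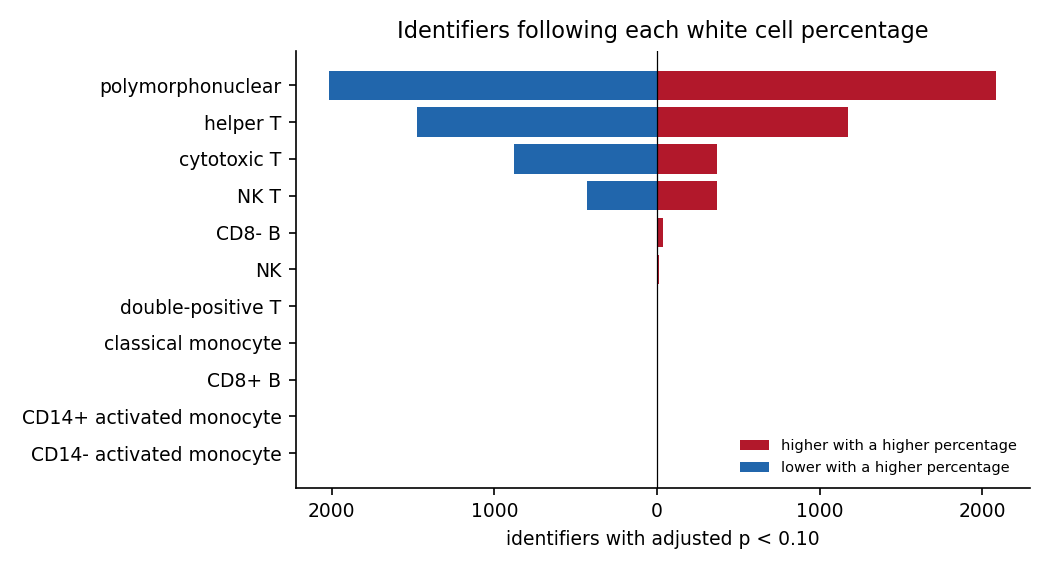
Number of identifiers (horizontal axis) whose expression followed each of 11 white cell percentages (vertical axis) across 42 females, split into those higher (right) and lower (left) in females with a higher percentage. Polymorphonuclear cells and helper T cells had the longest bars, 4101 and 2653 identifiers in both directions together.

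Cell-associated expression carried over between sequencing runs for some cell types. The 50 identifiers of highest correlation with a percentage in 1 flowcell, whether or not any passed a test there, were scored in the libraries of the other. The polymorphonuclear set scored in step with the polymorphonuclear percentage both when chosen in run0316 and scored in run0317 (Pearson r = 0.748, permutation p = 0.00014, n = 22) and the other way round (r = 0.886, permutation p = 1e-05, the smallest value the permutations can give, n = 20). Spearman's rho was 0.754 (permutation p = 0.00012) and 0.868 (permutation p = 1e-05), and r was 0.589 and 0.845 without the 2 libraries farthest from the median percentage. The helper T set gave r = 0.574 (permutation p = 0.0051) and r = 0.724 (permutation p = 0.00039), with rho 0.570 (permutation p = 0.00658) and 0.621 (permutation p = 0.00431), and r = 0.557 and 0.553 without the 2 farthest libraries. The CD8-negative B set gave r = 0.582 (permutation p = 0.00389) and r = 0.560 (permutation p = 0.0118), with rho 0.726 (permutation p = 0.00019) and 0.462 (permutation p = 0.0402). Without the 2 farthest libraries these were r = 0.689 and r = 0.117, so the second rested on those libraries. The cytotoxic T set gave r = 0.396 (permutation p = 0.0686) and r = 0.398 (permutation p = 0.0851), with rho 0.396 (permutation p = 0.07) and 0.550 (permutation p = 0.0138, adjusted p = 0.0321), and r = 0.371 and 0.616 without the 2 farthest libraries. The double-positive T set gave r = 0.313 (permutation p = 0.157) and r = 0.537 (permutation p = 0.00832), with rho 0.359 (permutation p = 0.102) and 0.439 (permutation p = 0.0528). The second r fell to 0.316 without the 2 farthest libraries and to 0.140 (permutation p = 0.486) with no count filter, where the first r of the cytotoxic T set also fell, to 0.219 (permutation p = 0.305). No relation past the threshold was found for the classical monocyte sets (r = 0.0675 and 0.0389) or the NK sets (r = -0.039 and 0.175). With no count filter the NK set chosen in run0317 had rho = 0.499 (permutation p = 0.0275, adjusted p = 0.0482) and r = 0.330 (permutation p = 0.154), against rho = 0.0361 with the filter. Of 14 such relations, 7 had an adjusted permutation p under 0.05 for r. Overlap between the sets of different cell types was not examined, so these relations need not be specific to 1 cell type.

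Double-positive T cells, which carry both CD4 and CD8, were more abundant in females of higher past rank. Their percentage ran from 0.17% to 38.27% (mean 3.11% ± 6.23, SD, n = 42). Its rank order followed past Elo (Spearman rho = 0.586, permutation p = 5e-05, adjusted p = 0.0011 over 22 relations of 11 cell types with 2 ratings). This permutation, like the others here not made within groups, ignored social group. Of the variance of past Elo 73.6% lay between social groups, so females are not independent of their groups in it. Median percentages were 2.91% in VBB_SGE2 and 2.89% in WXC_SGE2, the groups with the highest mean past ratings (1696 and 1377), and 0.325% in Jl11_SGE2, the group with the lowest (311). The groups between did not all follow this order: Fq9_SGE2, with a mean past rating of 1319, had a median of 1.13%, below the 1.19% of Bc8_SGE2 (671), and Pp10_SGE2 (341) had 0.97%, above the 0.805% of Aa11_SGE2 (765). Pearson's r over the same females was 0.272 (permutation p = 0.0624), because the percentages are strongly skewed; on log2 percentages it was 0.540 (permutation p = 0.00015). Within flowcells rho was 0.733 (run0316, permutation p = 0.00043) and 0.418 (run0317, permutation p = 0.0536), while r was 0.422 in run0316 (permutation p = 0.0283) and -0.0288 in run0317 (permutation p = 0.907). With both measures centred on the social group mean, r on log2 percentages was 0.325 and did not pass (p = 0.143, permutation within groups). Pearson's r without the 2 females farthest from the median rating was 0.257 (permutation p = 0.0991). The percentage also followed age (r = 0.523, permutation p = 0.0009, adjusted p = 0.0099 over 11 cell types; rho = 0.452, permutation p = 0.00271, adjusted p = 0.0298). The relation with age gave r = 0.646 in run0316 (permutation p = 0.00068) and r = 0.028 in run0317 (permutation p = 0.9), and r = 0.370 without the 2 females farthest from the median age (permutation p = 0.0179). On ranks it was rho = 0.554 in run0316 (permutation p = 0.0126) and rho = 0.41 in run0317 (permutation p = 0.059). Centred on social group means, the relation with age was r = 0.402 on log2 percentages (p = 0.0255, permutation within groups) and 0.428 on percentages (p = 0.0814). With age held in the ranks, the relation with past rating was rho = 0.452 (permutation p = 0.00274) over all females, in a test that ignores social group.

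**Figure D2:**
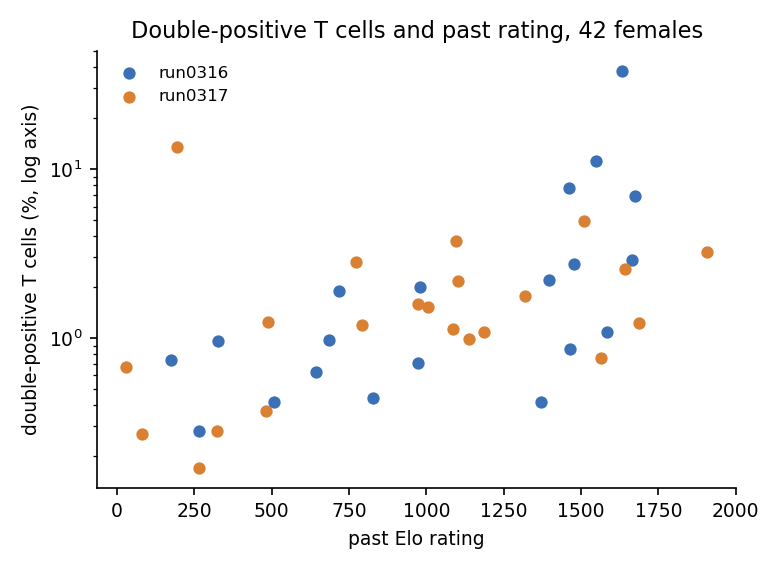
Percentage of double-positive T cells (vertical, log axis) against past Elo rating (horizontal) in 42 females, coloured by flowcell. Percentages were higher in females of higher past rating (Spearman rho 0.586), and the highest percentages were 38.27% and 13.44%.

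NK T cells made up 0.838% ± 0.423 (SD, n = 5) of cells in Pp10_SGE2, whose mean past rating of 341 was among the lowest, and between 0.103% and 0.45% on average in the other social groups. Jl11_SGE2, the group with the lowest mean past rating (311), had only 0.15%. NK cells were also most abundant in Pp10_SGE2, at 17.2% ± 8.38 (SD, n = 5), against group means of 4.52% to 8.08% elsewhere. Across all females the NK T percentage fell with past Elo (r = -0.410, permutation p = 0.00559; rho = -0.352, permutation p = 0.0233), but the adjusted p over the 22 relations was 0.123 for r and 0.256 for rho. The relation was r = -0.266 in run0316 (permutation p = 0.278) and r = -0.600 in run0317 (permutation p = 0.00148), r = -0.305 without the 2 females farthest from the median rating (permutation p = 0.0525) and r = -0.305 without Pp10_SGE2 (permutation p = 0.0611). With both measures centred on the social group mean it was r = 0.142, so the negative relation lay between social groups. None of the 11 cell percentages followed current Elo at an adjusted p under 0.05; the smallest permutation p was 0.0404, for double-positive T cells (r = 0.292, rho = 0.122, adjusted p = 0.444). For these cells r was 0.404 in run0316 and 0.125 in run0317, and 0.294 without the 2 females farthest from the median rating. The ordinal rank within the group gave r = 0.367 (permutation p = 0.00278, not adjusted). On log2 percentages r was 0.226 over all females (permutation p = 0.152) and 0.348 centred on the social group mean (p = 0.0539, permutation within groups).

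Current rank was compared among females with past rank, age, flowcell and cell composition held. In this additive fit no identifier passed an adjusted p under 0.10 in edgeR, while 1762 of 12223 had an unadjusted p under 0.05 (813 with a positive and 949 with a negative slope; 611 expected with no effect). DESeq2 called 55 and limma voom 0. With social group added to the fit, so that females were compared within their groups, 752 identifiers passed, 277 higher and 475 lower in higher-ranked females. The slopes of these 752 had the same sign in both fits, and without social group they were a median 0.849 times as large. Both fits use the libraries in which the 752 were chosen. Among the 752 the median absolute slope was 0.29 log2 units per SD of rating.

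Identifiers 203 and 828 were higher in females of higher current rank within their groups, and identifiers 114908 and 10550 were lower. Identifier 203 rose by 0.54 ± 0.108 log2 units per SD of current Elo (SE, n = 42, adjusted p = 0.0236), at low counts of 4 to 26 reads per library. Identifier 828 rose by 0.39 ± 0.078 (adjusted p = 0.0236), with a slope of 0.25 without Cw10_SGE2. Identifier 114908 changed by -0.59 ± 0.105 (adjusted p = 0.0211), with a slope of -0.39 in the additive fit, and identifier 10550 by -0.56 ± 0.10 (adjusted p = 0.0211). In each social group the highest-rated female was also set against the lowest-rated one. Identifier 203 was higher in the highest-rated female in 9 of 9 groups, by 1.01 ± 0.59 log2 units (SD, exact sign-flip permutation p = 0.0039, the smallest that 9 pairs allow). Identifier 114908 was lower in 8 of 9, by -1.44 ± 1.14 (exact permutation p = 0.0078). Identifier 828 was higher in 7 of 9 (exact permutation p = 0.0273) and identifier 10550 lower in 7 of 9 (exact permutation p = 0.0313). These pairs reuse the libraries in which the identifiers were chosen, so their p-values are not independent evidence. The count of 752 rested on single animals: it was 0 without Cw10_SGE2 replicate 4, 19 without Aa11_SGE2 replicate 4 and 32 without Aa11_SGE2 replicate 2, and the count of 0 in the additive fit became 897 without Fq9_SGE2 replicate 4. The fit with social group lost its calls without Aa11_SGE2, Cw10_SGE2 or Ze12_SGE2, and left 62 with no age term.

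**Figure D3:**
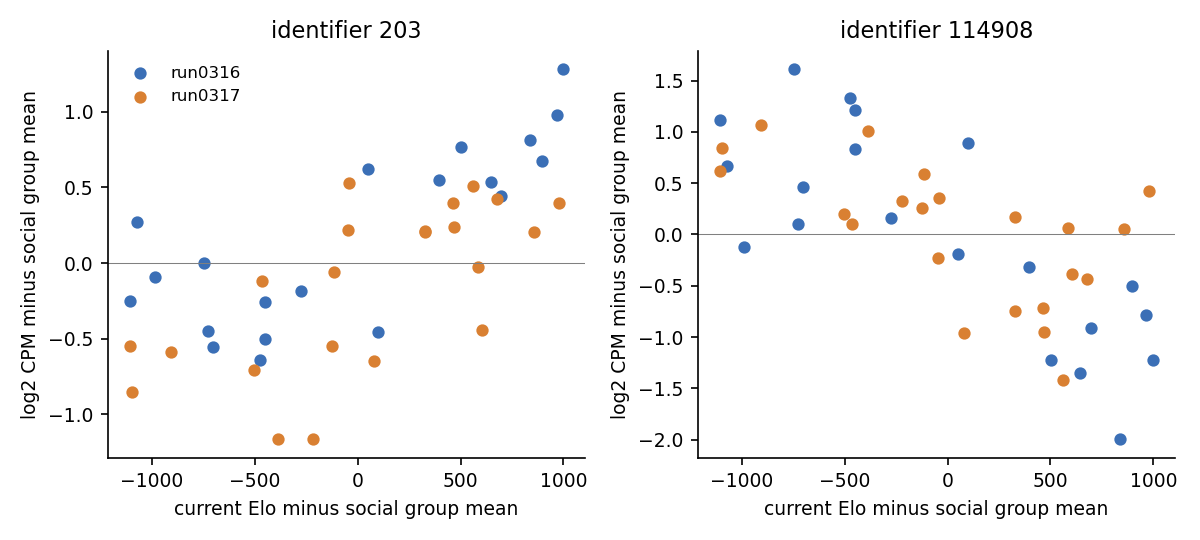
Expression (log2 CPM minus the mean of the female's social group, vertical) against current Elo minus the group mean (horizontal) for identifiers 203 (left) and 114908 (right) in 42 females, coloured by flowcell. The fitted slopes per SD of rating were 0.54 for identifier 203 and -0.59 for identifier 114908.

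Past rank, the rating from the earlier phase of the study, was associated with 655 identifiers in the additive fit, 334 higher and 321 lower in females of higher past rank. Identifier 84444 rose by 0.33 ± 0.066 log2 units per SD of past Elo (SE, n = 42, adjusted p = 0.0537) and identifier 5345 by 0.72 ± 0.145 (adjusted p = 0.0557). Identifier 5345 had 3 to 89 reads per library. Its slope was 0.52 without Jl11_SGE2, 0.55 with no age term and 0.60 with social group in the fit. Identifier 151188 changed by -0.28 ± 0.06 (adjusted p = 0.0557). Identifier 3467 changed by -2.12 ± 0.405 (adjusted p = 0.0537), with between 0 and 29 reads per library. Its slope was -1.19 with limma voom, -1.14 with social group as a random effect, -1.37 with no age term, -0.83 in run0317 alone and -1.29 without Jl11_SGE2. This identifier had 0 reads in most libraries. The 4 females of Jl11_SGE2 had 3 to 29 reads, and the highest count elsewhere was 11, in WXC_SGE2 replicate 3 (past rating 328). In Pp10_SGE2, with a mean past rating of 341 against 311 in Jl11_SGE2, replicate 1 had 1 read and the others 0. With social group in the fit the slope was 0.12 for identifier 84444 and -0.18 for identifier 151188. Identifier 84444 had a slope of 0.22 with no age term, and identifier 151188 one of -0.17 without Jl11_SGE2. The smallest adjusted p was 0.0537, so no identifier passed 0.05, and 2000 passed 0.20. Social groups differed widely in past rank: 73.6% of the variance of past Elo lay between them, against 2.97% for current Elo. With social group in the fit no identifier passed in edgeR (637 at an unadjusted p under 0.05) or limma voom, and DESeq2 called 5; 611 of the 655 slopes kept their sign, at a median 0.518 times their size. Leaving out age left 13 calls, with the slopes of all 655 of the same sign at a median 0.661 times their size and 488 at an unadjusted p under 0.05. Neither flowcell alone gave a call, but in run0316 alone 655 of the 655 slopes had the same sign at a median 1.07 times their size (479 at an unadjusted p under 0.05), and in run0317 alone 654 at 0.903 times (207). These slopes reuse libraries in which the 655 were chosen. The count was 0 without Jl11_SGE2, or without its replicate 3 or 4, and 3 without WXC_SGE2.

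The slopes on current and past rank were compared directly. For 704 identifiers the slope on current Elo differed from the slope on past Elo (adjusted p under 0.10), 292 with the higher value for current rank and 412 with the lower. With social group in the fit no identifier passed in edgeR (767 at an unadjusted p under 0.05) or limma voom, and DESeq2 called 6. With social group as a random effect 8 passed. When current ratings were exchanged within social groups, 7 of 39 draws gave as many calls as the additive fit. Across the 12223 genes, which are not independent replicates, the current and past slopes correlated at Pearson r = 0.159. Fits with current ratings exchanged within social groups gave r = -0.073 ± 0.272 (SD over 39 draws), with 7 of 39 at least as high. The covariance was 0.00696, against a mean of -0.00294 in those draws. The 752 calls for current rank came from the fit with social group, and the 655 for past rank from the additive fit. Between these lists from unlike fits 21 identifiers were shared, all with the same sign, where 40.3 were expected of independent lists.

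An interaction between current and past rank, the test of whether the slope on present rank depends on rank history, was called for 3 identifiers, all with a negative interaction. In this fit 590 identifiers had an unadjusted p under 0.05, where 611 were expected with no effect. Identifier 10512 had an interaction slope of -1.42 ± 0.25 (SE, adjusted p = 0.0178) and identifier 23251 one of -1.65 ± 0.323 (adjusted p = 0.0599). All 3 had 0 reads in several libraries, identifier 10512 in 13, identifier 23251 in 25 and the third in 17. They were chosen after their values were seen. Each was highest in VBB_SGE2 replicate 1 (current Elo 239, past Elo 1908) or Pp10_SGE2 replicate 2 (1997 and 30), females with strongly opposed ratings. Without the first of these females 1 identifier was called, and without the second 0. DESeq2 called 3 and limma voom 1. The count was 0 with a filter at a median CPM of 5 or more, and with social group in the fit no identifier passed in edgeR (709 at an unadjusted p under 0.05) or limma voom, while DESeq2 called 4.

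Age was associated with 1050 identifiers, 457 higher and 593 lower in older females, with a median absolute slope of 0.40 log2 units per SD of age (SD 4.06). Within social groups 990 passed, and the other settings given below for age are those of the additive fit. The smallest adjusted p of the additive fit was 0.0502. The slopes on age and past rank were opposed: 174 identifiers were called for both, 90 with a positive past slope and a negative age slope and 84 the other way. Both slopes come from 1 fit in which past rank and age are related, which by itself sets them against each other. Across genes their correlation was r = -0.699, and fits with past ratings permuted gave r = -0.424 ± 0.199 (SD over 39 draws), with 3 of 39 at least as negative. The covariance was -0.0549, against a mean of -0.0238 in those draws, with 2 of 39 at least as negative. The number of age calls was 1646 in run0316 alone and 0 in run0317 alone, 64 without cell composition, and 0 without the 5 libraries of over 50% multi-mapped reads, without WXC_SGE2, without WXC_SGE2 replicate 1 and without Fq9_SGE2 replicate 1.

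Social groups differed widely in expression. Expression of 5665 identifiers (46.3%) differed among the 9 social groups with current rank, age, flowcell and cell composition held, and the 3 cell composition components together were associated with 3845 (31.5%). Over the tested genes a median 30.3% of the variance of log2 expression lay between social groups, against 19.5% for groups with no effect. The labels used here give no date of blood sampling or library preparation. Biology of the groups therefore cannot be told apart from days shared by a group. Flowcell was associated with no identifier in edgeR (156 at an unadjusted p under 0.05) or limma voom, and DESeq2 called 1. All 5 libraries of WXC_SGE2 were in run0316. With social group in the fit flowcell was again associated with no identifier in edgeR (256 at an unadjusted p under 0.05) or limma voom, and DESeq2 called 1.

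**Figure D4:**
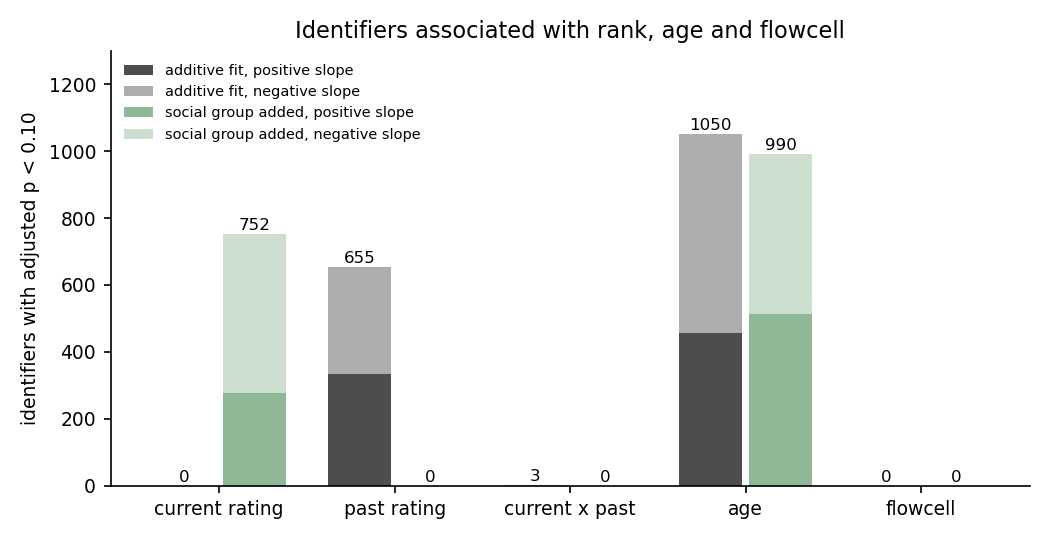
Number of identifiers with an adjusted p under 0.10 (vertical axis) for each term of the model (horizontal axis), in the additive fit (grey) and with social group added (green); the darker part of each bar is positive slopes and the paler part negative ones. Current rating had 0 and 752, past rating 655 and 0, and age 1050 and 990.

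The single identifier 3043 took a widely varying part of each library, from 2.44% to 62.0% of gene reads (mean 18.3% ± 16.2, SD, n = 42). It averaged 36.2% ± 17.5 (SD, n = 5) in Ze12_SGE2 and 3.93% ± 1.55 (SD, n = 5) in Fq9_SGE2, and the log2 share differed among the 9 social groups (43.5% of its variance, permutation p = 0.00983). Libraries with a larger log2 share had more reads aligned to several places (r = 0.887, rho = 0.891, permutation p = 1e-05 for each; r = 0.915 in run0316 and 0.837 in run0317; r = 0.873 without the 2 libraries farthest from the median). They had fewer identifiers detected (r = -0.737, rho = -0.736, permutation p = 1e-05 for each; r = -0.737 in run0316 and -0.752 in run0317; r = -0.712 without the 2 farthest libraries). The log2 share was not related to current Elo past the threshold (r = 0.273, permutation p = 0.0808; rho = 0.274, permutation p = 0.0799; adjusted p = 0.146 over 9 relations), with r = 0.502 in run0316 (permutation p = 0.0262), r = -0.0225 in run0317 (permutation p = 0.92) and r = 0.297 without the 2 females farthest from the median rating. With age it gave r = 0.329 (permutation p = 0.0332, adjusted p = 0.0747) and rho = 0.335 (permutation p = 0.0315). This was r = 0.543 in run0316, r = -0.137 in run0317 and r = 0.233 without the 2 females farthest from the median age (permutation p = 0.149). Centred on social group means, r was 0.401 with current Elo (p = 0.023), 0.319 with past Elo (p = 0.105) and 0.454 with age (p = 0.00899), by permutation within groups and without adjustment. The second most abundant identifier, 3303, took 0.00892% to 7.12% of gene reads. Its log2 share gave r = -0.218 with age (permutation p = 0.164, adjusted p = 0.185) and rho = -0.325 (permutation p = 0.0368, adjusted p = 0.0662), with r = -0.233 in run0316, -0.189 in run0317 and -0.120 without the 2 females farthest from the median age. Centred on social group means r was -0.414 with age (p = 0.00286), -0.239 with current Elo (p = 0.146) and -0.180 with past Elo (p = 0.278), by permutation within groups and without adjustment.

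**Figure D5:**
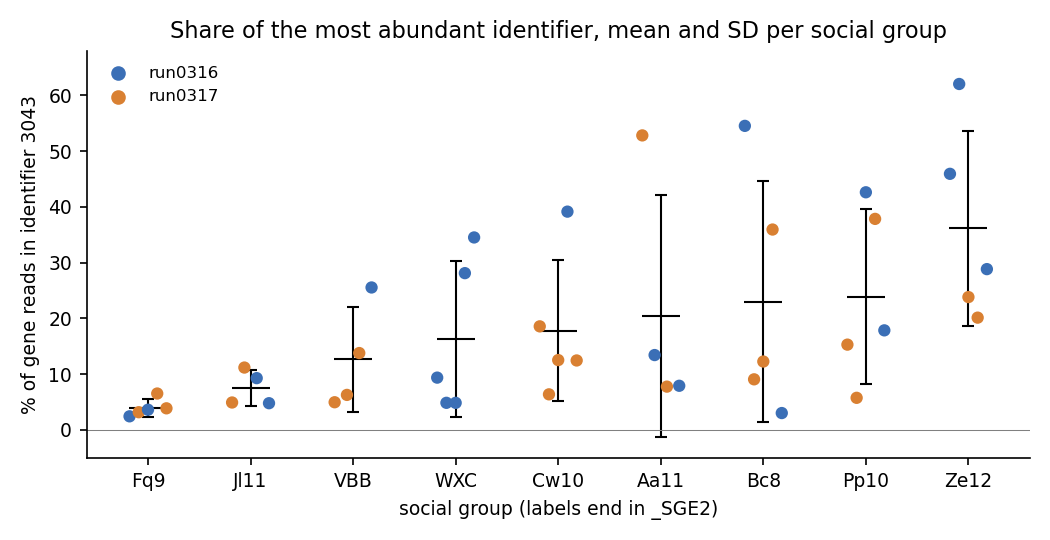
Percentage of gene reads taken by identifier 3043 (vertical axis) in each of 42 libraries, by social group (horizontal axis) and coloured by flowcell; the black line and bars are the mean and SD of each group. Ze12_SGE2 averaged 36.2% and Fq9_SGE2 3.93%.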

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

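Of the tests in this part, those of the share of identifier 3043 and of the 5 multi-mapped libraries were chosen after the results were seen. Exchanges of ages by social group were added once the age counts were known, with what they would show written down before they were run, and the other exchanges of ratings, ages and groups were set beforehand.

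Calls for current rank that appear once females are compared within social groups (752, against 0 in the additive fit) were set against 3 explanations. With the share of identifier 3043 as a covariate 260 calls were made and the slopes of all 752 kept their sign at a median 0.933 times their size (quartiles 0.886 and 0.983). Without the 5 libraries over 50% multi-mapped, 432 calls were made and the median was 1 (quartiles 0.918 and 1.08). Neither setting removed the slopes, but both reuse libraries in which the 752 were chosen, which favours slopes that stay. A part for either explanation therefore stays open. The share followed current Elo within groups (r = 0.401, p = 0.023 by permutation within groups, not adjusted). Chance was not excluded: when current ratings were exchanged within social groups, 2 of 40 assignments, the real one included, gave as many calls, the highest other giving 2476, several times the real count. Such a split points to a structure of the samples, which was not identified. The number at an unadjusted p under 0.05 was 1762, reached in 2 of 40 with 3040 the highest other. Rank itself stays open as an untested biological explanation.

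Past rank was associated with 655 identifiers in the additive fit. Permuting past ratings over all females given the other terms, which ignores social group, gave as many calls in 1 of 40 assignments (highest other 31), so chance was excluded only where females are taken as independent of their groups. Exchanging the mean past ratings of whole social groups gave as many calls in 10 of 40 assignments (highest other 3780, several times the real count, which points to a structure of the samples), so differences between social groups unrelated to rank may produce a count of this size. A part for rank history stays open, because past rank and social group largely overlap, and so does a part for age, to which past rank is related.

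The share of identifier 3043 ran from 2.44% to 62.0% of gene reads. A difference between flowcells was not found (permutation p = 0.399, 1.78% of the variance of the log2 share). The share followed all reads in the table in part (Pearson r = 0.547, 95% interval 0.292 to 0.730, permutation p = 0.0002). Within flowcells r was 0.580 in run0316 and 0.456 in run0317. Of depth as the cause, r over 0.8 was asked, a limit set after the data were seen. All reads include the multi-mapped reads, which themselves rose with the share. A part for depth therefore stays open. The share differed among social groups (permutation p = 0.00983). Whether that is biology of the groups or the day of blood sampling or library preparation could not be tested, since the labels used here give neither date.

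Other counts were tested the same way. For age (1050 calls) the permutation of ages over all females given the other terms, which ignores social group, gave as many in 1 of 40 assignments (highest other 4), which excludes chance only under that same assumption. Exchanging the mean ages of whole social groups gave as many calls in 11 of 40 (highest other 4233), so differences among social groups unrelated to age may produce a count of this size. With social group in the fit (990 calls) and ages exchanged within groups, chance was excluded (1 of 40, highest other 16). Chance was also excluded for social group (5665 calls, 1 of 40, highest other 716). That test does not separate biology of the groups from shared days of blood sampling or library preparation. Chance was not excluded for the difference between current and past slopes (704 calls; 8 of 40, highest other 2869) or for the interaction, a test of whether past rank alters the slope on current rank (3 calls; 6 of 40, highest other 1753). In these too the highest split lay above the real count, several times for the difference of slopes and far more for the interaction. This points to a structure of the samples that was not identified.

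In 216 tests over 24 quantities and 9 social groups, 19 values lay far from the others of their group, where chance gives about 5% of groups. That share does not apply to the 5 values of identifier 3467 among them, given below. Among cell percentages, double-positive T cells reached 38.27% in WXC_SGE2 replicate 4 (next 6.89%) and 13.44% in Pp10_SGE2 replicate 1 (next 1.89%). NK cells reached 19.66% in VBB_SGE2 replicate 2 and 12.87% in Jl11_SGE2 replicate 2, NK T cells 0.32% in Ze12_SGE2 replicate 3, and Aa11_SGE2 replicate 2 had 9.08% CD8-negative and 1.53% CD8-positive B cells. Identifier 3043 took 52.82% of gene reads in Aa11_SGE2 replicate 1, where the next animal had 13.43%. Reads assigned to genes stood at 13399412 in Ze12_SGE2 replicate 5, and all reads at 22978146 in Jl11_SGE2 replicate 1 and 30072420 in WXC_SGE2 replicate 5. The multi-mapped share was 26.31% in Fq9_SGE2 replicate 1. Log2 CPM of identifier 84444 was 5.97 in Pp10_SGE2 replicate 3 and of identifier 114908 8.98 in Jl11_SGE2 replicate 1. Identifier 3467 stood above the floor in a single animal of 5 groups, at log2 CPM -1.53 (Aa11_SGE2 replicate 1), -1.62 (Bc8_SGE2 replicate 5), -1.81 (Pp10_SGE2 replicate 1), -1.85 (VBB_SGE2 replicate 4) and -1.36 (Ze12_SGE2 replicate 4). These animals had 1 or 2 reads of it, and the others of their groups were tied at 0 reads, so a single read was enough for a flag. Outside the gene rows, 35.4% of all reads aligned to more than 1 place, 23.2% lay in no feature and 1.62% were ambiguous.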

How the results depend on the processing

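Chosen after the data were seen were settings with identifier 3043, the 5 multi-mapped libraries and further settings of the fit with social group. So were the left-out animals and social groups for the correlation of slopes. The others were planned, among them the fit with social group itself. The cause of each change was not tested. Counts moved more than directions. The 752 slopes for current rank with social group kept their sign in each setting of tool, filter, covariate and library choice in which they were tested, at a median 0.716 times their size with no age term. The 655 slopes for past rank did so except for social group in the fit (611 of 655, median 0.518 times) and run0317 alone (654), and were a median 0.661 times their size with no age term. For the 752, signs were counted for 1 library choice, leaving out the 5 multi-mapped libraries, and in neither flowcell alone. Both sets of slopes were refitted in all or part of the libraries in which the identifiers were chosen. This favours kept signs, which are therefore no independent evidence. The smallest adjusted p was 0.0537 for past rank and 0.0502 for age. No paired analysis was possible by replicate number, because these numbers only follow the order of the deposit and tie no animals across social groups. The gene list tests and marker list scores were not run. Counting depth limits identifiers with few reads, such as 203 and 3467.

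Current rank (0 calls) gave 55 with DESeq2, 1 with no count filter, 752 with social group in the fit, 150 with social group as a random effect, 1 in run0316 alone and 1 at an adjusted p under 0.20. It gave 1186 without Fq9_SGE2 and 443 without Jl11_SGE2. Leaving out single animals gave 0 to 897, with 897 without Fq9_SGE2 replicate 4, 2 without WXC_SGE2 replicate 5, 1 without Bc8_SGE2 replicate 4 and 0 otherwise.

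Current rank with social group in the fit (752) gave 222 and 1806 at 0.05 and 0.20, 1324 with DESeq2, 302 with no cell composition, 62 with no age term, 260 with the share of identifier 3043 as covariate and 432 without the 5 multi-mapped libraries. It gave 0 without Aa11_SGE2, Cw10_SGE2 or Ze12_SGE2, 341 without VBB_SGE2 and 1530 without Pp10_SGE2. Single animals left out gave 0 to 1654. The 15 that moved the count over 1.5 times were Cw10_SGE2 replicates 4 (0), 1 (215), 3 (227) and 5 (341), Aa11_SGE2 replicates 4 (19) and 2 (32), VBB_SGE2 replicate 1 (139), Fq9_SGE2 replicates 1 (308) and 4 (1559), Jl11_SGE2 replicate 1 (386), Pp10_SGE2 replicates 3 (463) and 2 (1607), Ze12_SGE2 replicate 1 (476), WXC_SGE2 replicate 4 (487) and Bc8_SGE2 replicate 3 (1654).

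Past rank (655) gave 1269 with DESeq2, 387 with no count filter, 285 with 5 cell components, 0 with social group as coefficients or as a random effect, 13 with no age term, 0 in either flowcell alone, 1053 with ordinal current rank, 174 without the 5 multi-mapped libraries, and 0 and 2000 at 0.05 and 0.20. It gave 321 without Cw10_SGE2, 0 without Jl11_SGE2, 2059 without VBB_SGE2 and 3 without WXC_SGE2. Single animals left out gave 0 to 1944, and 23 moved the count over 1.5 times: Jl11_SGE2 replicates 3 and 4 (0), 2 (108) and 1 (127), Fq9_SGE2 replicates 3 (154), 1 (222), 5 (363) and 4 (1268), WXC_SGE2 replicates 2 (182), 3 (219) and 5 (302), Pp10_SGE2 replicates 4 (201), 1 (256) and 2 (1410), Cw10_SGE2 replicates 2 (259) and 1 (341), Aa11_SGE2 replicate 3 (344), Ze12_SGE2 replicates 2 (354), 5 (385) and 3 (1061), VBB_SGE2 replicates 2 (366) and 1 (1944) and Bc8_SGE2 replicate 3 (1037).

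The difference between current and past slopes (704) gave 1394 with DESeq2, 1267 with 5 cell components, 0 with social group in the fit, 8 with it as a random effect, 352 with no age term, 0 in either flowcell alone, 32 with ordinal rank, 386 with the share of identifier 3043 as covariate, 84 without the 5 multi-mapped libraries, and 116 and 2101 at 0.05 and 0.20. It gave 15 without Cw10_SGE2, 13 without Fq9_SGE2, 21 without Jl11_SGE2, 1574 without Pp10_SGE2, 2171 without VBB_SGE2, 385 without WXC_SGE2 and 1510 without Ze12_SGE2. Single animals left out gave 56 to 2297, and 16 moved it over 1.5 times: Jl11_SGE2 replicates 1 (56), 4 (237), 2 (259) and 3 (370), Cw10_SGE2 replicates 5 (167) and 4 (442), Fq9_SGE2 replicates 3 (168), 1 (408), 5 (421), 4 (432) and 2 (1189), Ze12_SGE2 replicates 1 (304) and 3 (1641), WXC_SGE2 replicate 2 (465), VBB_SGE2 replicate 1 (2197) and Pp10_SGE2 replicate 2 (2297).

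The interaction (3) gave 1 with limma voom, 19 with no count filter, 0 at a median CPM of 5 or more, 1 with no cell composition, 0 with social group in the fit, 1 with it as a random effect, 13 with no flowcell term, 0 in run0316 alone, 0 with the share of identifier 3043 as covariate, 1 without the 5 multi-mapped libraries, and 1 and 5 at 0.05 and 0.20. It gave 1 without Aa11_SGE2, 12 without Fq9_SGE2, 5 without Jl11_SGE2 and 0 without Pp10_SGE2. Single animals left out gave 0 (Pp10_SGE2 replicate 2) to 17 (Fq9_SGE2 replicate 4), with 1 without Bc8_SGE2 replicate 2, Fq9_SGE2 replicate 3, Pp10_SGE2 replicate 3 or 4, VBB_SGE2 replicate 1 or 2, or WXC_SGE2 replicate 5, 5 without Bc8_SGE2 replicate 1, Fq9_SGE2 replicate 2, Jl11_SGE2 replicate 3 or WXC_SGE2 replicate 1, and 6 without Ze12_SGE2 replicate 5.

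Age (1050) gave 1778 with DESeq2, 64 with no cell composition, 2412 with no flowcell term, 1646 in run0316 alone and 0 in run0317 alone, 1622 with ordinal rank, 1630 with the share of identifier 3043 as covariate, 0 without the 5 multi-mapped libraries, and 0 and 2901 at 0.05 and 0.20. It gave 404 without Aa11_SGE2, 410 without Bc8_SGE2, 335 without Cw10_SGE2, 1746 without Fq9_SGE2, 174 without Jl11_SGE2, 602 without Pp10_SGE2, 496 without VBB_SGE2 and 0 without WXC_SGE2. Single animals left out gave 0 to 2791, and 20 moved it over 1.5 times: Fq9_SGE2 replicates 1 (0), 3 (652) and 4 (2791), WXC_SGE2 replicates 1 (0) and 3 (492), Cw10_SGE2 replicate 3 (117), Jl11_SGE2 replicates 4 (349), 3 (539) and 1 (643), Aa11_SGE2 replicate 4 (352), Pp10_SGE2 replicates 5 (462) and 2 (1576), VBB_SGE2 replicates 4 (493), 1 (594) and 2 (1778), Bc8_SGE2 replicates 2 (543), 1 (684) and 3 (1842) and Ze12_SGE2 replicates 2 (554) and 3 (1700).

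The correlation of current and past slopes (0.159) was -0.154 with no age term, -0.079 without Jl11_SGE2, -0.025 without Pp10_SGE2, -0.072 without VBB_SGE2, -0.0080 without Ze12_SGE2 and 0.513 without Fq9_SGE2, and -0.079 (Pp10_SGE2 replicate 2) to 0.420 over single animals left out, negative also without VBB_SGE2 replicate 1. The number of cell percentages related to a rating (0 by Pearson's r) was 1 by rank correlation and 1 in run0317 alone. The social group count stayed within 1.5 times with RLE size factors, limma voom, no cell composition and at 0.05.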

Other observations

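The tests in this part were chosen after the data were seen. For each of 7 cell percentages, the 50 identifiers of highest correlation with it within social groups, whether or not any passed a test, were set against the slopes of all genes on current rank, past rank and age, with and without social group, in 6 families of 7 set tests. In 4 sets not all members had passed singly, since over all libraries edgeR called 0 identifiers for classical monocytes (751 at an unadjusted p under 0.05; limma voom 0), 1 for double-positive T, 10 for NK and 39 for CD8-negative B cells. All 50 identifiers of the double-positive T set had a positive slope on current rank (median 0.19 log2 units per SD, n = 42), and 46 of the 50 of the CD8-negative B set a negative one (median -0.15), in fits that already held cell composition. With the preset correlation of camera in limma the adjusted p was 2.05e-19 and 7.13e-08 over 7 sets. With an estimated correlation (0.455 and 0.386 between genes) neither passed: adjusted p = 0.177 and adjusted p = 0.467. These sets were chosen in the same libraries, in which the double-positive T percentage itself had a group-centred r of 0.362 with current Elo, so the slopes are no independent evidence. The same holds for the mean score of the double-positive T set in fits without cell composition, which did not pass an adjusted p of 0.05 on current rank: 0.446 ± 0.152 SD per SD (SE, permutation p = 0.00573, adjusted p = 0.0802 over 14 relations), and 0.481 ± 0.152 with social group held (permutation p = 0.00374, adjusted p = 0.0524). Without the animal at 38.27% double-positive T cells, and with the set chosen again, which left 25 of 50 identifiers shared, the score slope without social group was 0.452 ± 0.154 (SE, n = 41, permutation p = 0.00651, not adjusted). Camera for current rank with social group held and an estimated correlation gave an adjusted p = 0.0945 for the double-positive T set and 0.91 for the CD8-negative B set. The polymorphonuclear set there had 44 of 50 positive slopes, with an adjusted p = 0.00484 with the preset correlation and adjusted p = 0.942 with an estimated one.

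With social group held, 1 of the 7 sets passed on past rank with an estimated correlation, in a model that called no single identifier for past rank in edgeR (637 at an unadjusted p under 0.05) or limma voom and 5 in DESeq2. In this set, of classical monocytes, which no identifier followed past the threshold, 48 of 50 identifiers had a negative slope (median -0.31), with an adjusted p = 0.0219 with an estimated correlation and 8.56e-23 with the preset one. This was the smallest of the 42 p-values with an estimated correlation, and the adjustment covers only the 7 sets of its family. The other sets passed only with the preset correlation or not at all. The polymorphonuclear set had 47 of 50 negative slopes (adjusted p = 3.85e-17 with the preset correlation and adjusted p = 0.196 with an estimated one). The helper T (49 of 50), cytotoxic T (43), double-positive T (43) and CD8-negative B (41) sets were mostly positive, with preset adjusted p of 6.22e-14, 1.04e-05, 0.00157 and 0.00938 and adjusted p of 0.204, 0.233, 0.475 and 0.61 with an estimated correlation. In fits without cell composition the mean score passed neither for the monocyte set (-0.444 ± 0.30, SE, permutation p = 0.151, adjusted p = 0.854) nor for the polymorphonuclear set (-0.124 ± 0.362, permutation p = 0.735, adjusted p = 0.854). Sets chosen for monocytes in 1 flowcell did not track the monocyte percentage in the other (r = 0.0675, permutation p = 0.764, and r = 0.0389, permutation p = 0.873). In the additive fit, without social group, 38 of the 50 were negative (adjusted p = 0.98 with an estimated correlation and 0.0244 with the preset one). On age no set passed with an estimated correlation (adjusted p = 0.874 or more). With the preset correlation 2 sets passed in the additive fit, NK (36 of 50 positive, adjusted p = 0.0164) and helper T (33 of 50 negative, adjusted p = 0.0164). With social group held these were NK (40 of 50 positive, adjusted p = 0.000673) and double-positive T (45 of 50 negative, adjusted p = 0.00192).

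The correlation of NK cell percentages with current Elo had opposite signs in the 2 flowcells, of which the first did not pass. It was r = -0.367 in run0316 (n = 20, permutation p = 0.114) and r = 0.522 in run0317 (n = 22, permutation p = 0.0117). For the difference in r, permuting flowcell labels gave a permutation p = 0.00712, with an adjusted p = 0.157 over 22 relations. CD8-negative B cells were negatively related to age within social groups (group-centred r = -0.479, p = 0.012 by permutation within groups, not adjusted over the 11 cell types), while the pooled relation was r = -0.142 (permutation p = 0.371, adjusted p = 0.71).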
